A study of Mus musculus with 6 samples.

How the data were processed

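Gene expression was measured with 6 short-oligonucleotide arrays in ventricular tissue of mice that were 8 weeks old. Per the labels, 3 arrays came from wild-type mice and 3 from mice with a heart-specific transgene that keeps an activated form of the kinase Akt on (caAkt). Per the labels' protocols, total RNA was extracted with Trizol, purified on RNeasy columns and labelled with biotin in a single-cycle reaction. The deposited table holds 1 log2 value per probe set and array, and per the submitters' processing notes the authors made these log2 values with RMA in the R package affy. RMA corrects the background, makes the distributions of the arrays alike by quantile normalization and summarises the probes of a probe set on the log2 scale. It therefore compares genes relative to the bulk of the array, and a change shared by most genes would not be seen. Versions of RMA and affy were not given in the sources used here, nor was the scanner setting. The labels do not say that each array came from a separate heart, so the p-values of single genes measure the spread between these samples, which may be technical. No batch, date, hour of collection or sex was given in the labels. The number of arrays, 3 per group, limits the precision.

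The table held 45101 probe sets, of which 64 were controls. Probe sets were named through the platform annotation of 2016: 34945 had 1 gene symbol, 932 had several and 9160 had none there. The gene identifiers of 34741 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. No coordinates were used. Each of 18193 genes was represented by its probe set with the highest mean log2 value over the 6 arrays, with control probe sets and those with several symbols or no symbol left out and no filter on dim probe sets.

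Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, genotype as the term), with 4 residual degrees of freedom and Benjamini-Hochberg adjustment over the 18193 genes. A gene was called changed at an adjusted p under 0.05, and a log2 fold change is caAkt minus wild-type. Errors of fold changes are the moderated standard errors, and errors of levels are SDs over the 3 arrays of a group. For 45 gene lists, the members were fixed before the data were examined. Of these, 44 had at least 5 measured members and were tested, together with a combined list of the respiratory chain and ATP synthase subunits, which makes 45 tests. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 45 tests. With the preset, a list is judged against the spread between genes, so its p-value does not measure the spread between samples. An adjusted p given with a list is from this test unless another is named. Camera was repeated with the correlation estimated from the data, which bases the test on the 4 residual degrees of freedom, and fry was run as a self-contained test. For each list described with counts, a second count rests on p-values adjusted over the list alone.

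The genes named follow a rule fixed before the data were examined. It names Akt1 with every probe set, the 12 genes with the largest rise and the 12 with the largest fall among called genes with non-overlapping groups, and up to 4 members with the smallest p per list. It also names all regulators of mitochondrial genes, the sex-linked genes, and Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Pdk4, Slc2a1 and Slc2a4. Symbols of uncharacterised genes were left out of the ranked part. Where 5 or fewer members of a list changed in a direction, the members that this rule does not name were added after their values were seen, as were the clock genes outside it.

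The alternatives tried were eBayes with trend and robust settings, the mean of a gene's probe sets, only plain probe sets (names not ending in _x_at, _s_at or _a_at), all probe sets as rows, a filter on dim probe sets, a repeated quantile normalization, median centring, array weights, the replicate number as a block, a threshold of 0.01, and leaving out each array in turn. The counts and medians of the gene lists under these fits were added after the data were seen. A planned pseudocount was not needed because the values are already on the log2 scale. Exact permutation tests were used for single values of 3 against 3 arrays, where the smallest possible two-sided p is 0.1. Differences between the medians of lists were tested with 100000 permutations of the genes. These permutations treat genes as independent, whereas members of a list are correlated across arrays (estimated correlation 0.56 for fatty acid oxidation and 0.45 for sarcomere genes). Their p-values therefore do not measure the spread between samples.

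The steps were tested on simulated data. For the comparison of caAkt with wild-type, 200 of 18193 simulated genes were given a change. At a log2 size of 0.5, 65 of 67 genes (97.0%) were recovered with the right direction, and at sizes of 1 and 2 all 67 and all 66 were. There were 13 false calls. A simulated list with a shift was recovered by camera with the preset correlation and with an estimated one, and 1 other list was called with the preset correlation and 0 with the estimated one. The simulated genes varied independently, unlike members of the real lists, so the simulation cannot tell whether the preset correlation suits the real lists. Estimated from the data, the correlation ran from -0.05 for lung and thymus markers to 0.71 for ATP synthase. It was 0.57 for oxidative phosphorylation and 0.56 for fatty acid oxidation, well above the preset of 0.01. With estimated correlations, 0 of 45 lists were called.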

Results

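Ventricular expression was compared between 3 wild-type and 3 caAkt arrays, to ask which genes and pathways, mitochondrial ones in particular, differ in hearts with an activated Akt. The RMA log2 values had medians of 6.77 to 6.80 per array and spanned 3.17 to 15.45. Across all probe sets, which are not independent replicates, the correlation was 0.995 to 0.997 between arrays of the same genotype and 0.983 to 0.985 between genotypes. The 3' minus 5' signal of the actin control was 0.64 ± 0.06 (log2, SD, n = 3) in wild-type and 0.60 ± 0.08 in caAkt (exact permutation p = 0.5). For Gapdh it was -0.05 ± 0.01 and -0.03 ± 0.02 (exact permutation p = 0.3), and 0.1 is the smallest p this design allows. Xist stood at 11.36 to 11.47 on all 6 arrays, and the Y-linked genes Eif2s3y, Kdm5d and Uty at 3.87 to 4.57, a level at or above that of 8.10% of genes. High Xist with such low Y-linked signals is the pattern of female mice, and it held in both groups.

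Akt1, the kinase carried by the transgene, had 4 probe sets. One of them stood at 9.92 ± 0.22 (SD, n = 3) in wild-type and 15.11 ± 0.04 in caAkt hearts, a log2 fold change of 5.19 ± 0.11 (SE, adjusted p = 3.06e-08), or at least 36.5-fold. A second, at a higher level in wild-type, went the other way, from 10.71 ± 0.02 to 10.42 ± 0.11 (log2 fold change -0.29 ± 0.08, adjusted p = 0.0281 in the fit of all probe sets). The values of the remaining probe sets (-0.21 ± 0.09, adjusted p = 0.140; 0.08 ± 0.07, adjusted p = 0.490) were not called. The signal of 15.11 lies near the top of the scale (highest values 15.32 to 15.45 per array), so this fold is read as a lower bound. Which part of the transcript each probe set covers was not analysed here.

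**Figure D1:**
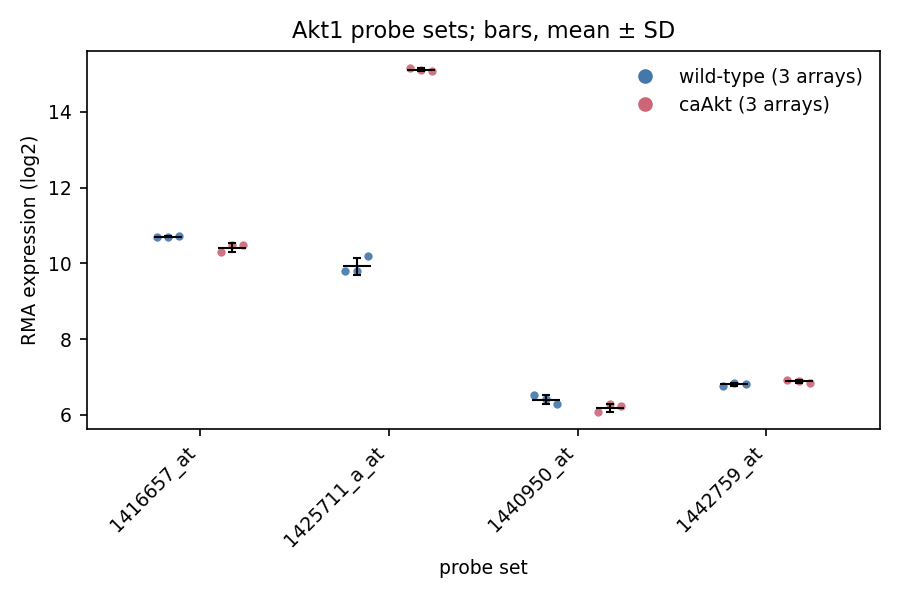
RMA expression (log2, vertical axis) of the 4 Akt1 probe sets (horizontal axis) on each array, with points for arrays (blue wild-type, red caAkt) and bars for the mean ± SD of 3 arrays. For the probe set that rose, the caAkt arrays lie at 15.08 to 15.16 against 9.79 to 10.18 in wild-type, while the largest difference of the others is -0.29.

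Of 18193 genes, 5183 (28.5%) were changed in caAkt hearts, 2929 higher and 2254 lower. After a renewed quantile normalization of the values, 2669 were higher and 2708 lower, so that which direction held more genes depended on the scaling. A change of at least 2-fold was seen for 626, with 451 higher and 175 lower. The 3 values of 1 group lay entirely above or below those of the other for 7717 genes (42.4%, against 10% by chance), among them 5138 of the changed genes.

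After Akt1, the largest rise was that of Cilp, a matrix protein of cartilage and scar tissue, with a log2 fold change of 5.14 ± 0.19 (SE, adjusted p = 5.26e-07). Timp1, an inhibitor of matrix metalloproteinases, rose by 4.24 ± 0.15. Nmrk2, a nicotinamide riboside kinase of striated muscle, rose by 4.10 ± 0.11, and Lgals3, which encodes galectin-3, by 4.08 ± 0.08. These rises are 18.8-fold, 17.2-fold and 17.0-fold. Next came the ubiquitin hydrolase Uchl1 (log2 fold change 3.80), Ltbp2 (3.62) and Tnc (3.49) of the matrix, the macrophage membrane protein Ms4a7 (3.43) and the acute-phase serpin Serpina3n (3.41). The potassium channel Kcnj14 (3.40) and the macrophage elastase Mmp12 (3.37) complete the list, and the adjusted p of these 11 genes was 3.08e-06 or less. The largest fall was that of Myot, the Z-disc protein myotilin, from 10.76 ± 0.32 to 5.88 ± 0.26 (log2 fold change -4.88 ± 0.17, adjusted p = 5.26e-07). Bex1 followed with a log2 fold change of -4.20 ± 0.19 and the carboxylesterase Ces1d with -3.89 ± 0.39 (adjusted p = 0.000101). The splicing factor Rbfox1 (-2.99), the angiotensin receptor Agtr1a (-2.80), the carbonic anhydrase Car14 (-2.64), the ephrin Efnb3 (-2.53) and Amy1 (-2.49) were lower too. So were the glutathione transferase Gstk1 (-2.49), Rpl3l (-2.40), a ribosomal protein of striated muscle, and the kinase Mylk4 (-2.37). Ttll1 fell by 3.44 on the log2 scale at its brightest probe set, whereas its other probe sets gave -0.15 and -0.10 and were not called.

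Genes of oxidative phosphorylation were lower as a group. Of 76 measured subunits of the respiratory chain and ATP synthase, 37 fell and 2 rose (45 and 2 adjusted over the list alone), with a median log2 fold change of -0.23 (adjusted p = 2.36e-10; adjusted p = 0.447 with an estimated correlation). Without wild-type replicate 2, 24 fell, and without wild-type replicate 3, 47 fell. In complex I, 21 of 34 subunits fell and 0 rose (28 and 0 adjusted over the list alone; 14 to 27 fell without single arrays), with a median of -0.30 (adjusted p = 1.25e-09; adjusted p = 0.406 with an estimated correlation). Ndufs4, Ndufs1 and Ndufv1 fell by 0.75 ± 0.08, 0.65 ± 0.07 and 0.59 ± 0.06 on the log2 scale. In complexes II and III, 8 of 14 fell and 0 rose (9 and 0 adjusted over the list alone; 5 fell without wild-type replicate 2). The median there was -0.24 (adjusted p = 0.000597; adjusted p = 0.447 with an estimated correlation), and Sdha fell by 0.41 ± 0.07. Of 15 ATP synthase subunits, 5 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.14 (adjusted p = 0.00577; adjusted p = 0.543 with an estimated correlation). These were Atp5g2 (-0.52), Atp5e (-0.49), Atp5j (-0.39), Atp5k (-0.25) and Atp5c1 (-0.28), the last chosen after its value was seen. Only 3 were called without wild-type replicate 2 or caAkt replicate 1, where Atp5k was lost (adjusted p = 0.0800 and 0.0636), and the call of Atp5c1 held only without wild-type replicate 3 (adjusted p up to 0.134 without any other array). Complex IV was mixed and not called (median -0.13, adjusted p = 0.143). The striated-muscle subunits Cox8b (-0.70) and Cox7a1 (-0.54) fell, while Cox8a (0.37) and Cox6a1 (0.54), which are expressed widely, rose. Cox6a2 fell by 0.30, was chosen after its value was seen and was not called without wild-type replicate 2 (adjusted p = 0.0530). In the complex IV list 2 of 13 rose and 3 fell, also adjusted over the list alone. Without wild-type replicate 3, 5 fell and the list was called (median -0.18, adjusted p = 0.0414). The median wild-type level was 13.77 for complex I, 14.13 for complexes II and III, 14.42 for ATP synthase and 14.44 for complex IV. The complexes with smaller falls thus lay closer to the top of the scale, where a fall may be understated. The values cannot show whether ATP synthase and complex IV changed less.

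Genes of fuel oxidation upstream of the respiratory chain were lower too. Of 22 genes of mitochondrial fatty acid import and β-oxidation, 20 fell (21 adjusted over the list alone), with a median log2 fold change of -0.58 (adjusted p = 2.36e-10; adjusted p = 0.355 with an estimated correlation). The isomerase Eci1 fell by 1.11 ± 0.08 (adjusted p = 1.53e-05), Crat by 0.86 ± 0.08, the electron carrier subunit Etfb by 0.83 ± 0.07 and Echs1 by 0.77 ± 0.07. The only member that rose, Cpt1a, the form of the carnitine transferase that predominates in liver, had a log2 fold change of 0.56 ± 0.09 and was chosen after its value was seen. In the tricarboxylic acid cycle and pyruvate dehydrogenase list, 15 of 18 fell and 0 rose (16 and 0 adjusted over the list alone; 11 to 16 fell without single arrays), with a median of -0.41 (adjusted p = 2.96e-07; adjusted p = 0.351 with an estimated correlation). Idh2 fell by 1.34 ± 0.10, Suclg2 by 0.96 ± 0.08, Fh1 by 0.65 ± 0.08 and Got2 by 0.48 ± 0.06. Catabolism of ketone bodies and branched-chain amino acids showed the lowest median of the 45 tests, -0.73, with 19 of 22 genes lower and 0 higher (22 and 0 adjusted over the list alone; adjusted p = 2.73e-13; adjusted p = 0.279 with an estimated correlation). The phosphatase Ppm1k, which activates the branched-chain ketoacid dehydrogenase, fell by 1.56 ± 0.09, its subunit Bckdhb by 1.21 ± 0.07, Mmut by 1.21 ± 0.07 and Ivd by 1.01 ± 0.07. For uptake, storage and release of fatty acids, 9 of 16 fell and 2 rose, also adjusted over the list alone, with a median of -0.33 (adjusted p = 0.0149; adjusted p = 0.447 with an estimated correlation). Dgat2, which makes triglycerides, fell by 1.96 ± 0.13. The lipid droplet protein Plin5 fell by 0.77 ± 0.13, whereas Plin2 rose by 0.37 ± 0.07. The lipase inhibitor Angptl4 rose by 2.41 ± 0.20 at its brighter probe set and had a value of 0.10 at another, which stood at 3.68 and 3.77, under the Y-linked signal.

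Mitochondrial ribosomal protein genes were lower in 40 of 72 cases (48 adjusted over the list alone; 28 to 41 without single arrays), with a median of -0.26 (adjusted p = 1.16e-08; adjusted p = 0.392 with an estimated correlation). Mrpl23 and Mrps28 fell by 0.66 ± 0.07 and 0.61 ± 0.07, and the only member that rose over all genes, Mrps6, had a log2 fold change of 0.35 and was chosen after its value was seen. Cytosolic ribosomal proteins had a median of 0.02 (adjusted p = 0.242; -0.02 without wild-type replicate 3) over 35 genes and were not called. Of 14 genes of mitochondrial fusion, fission and mitophagy, 5 fell and 0 rose, also adjusted over the list alone (median -0.19, adjusted p = 0.0204; adjusted p = 0.329 with an estimated correlation; median -0.12 without wild-type replicate 1). The mitophagy kinase Pink1 fell by 0.96 ± 0.09, the fusion protein Mfn1 by 0.66 ± 0.06 and the protease Oma1 by 0.51 ± 0.08. Opa1 fell by 0.31, though the mean of its probe sets was -0.10 and not called. Phb2 fell by 0.24, was chosen after its value was seen, and was called only without wild-type replicate 3 or caAkt replicate 3 (adjusted p up to 0.0957 without others). The list of energy transfer genes (creatine kinases and nucleotide carriers) was not called (adjusted p = 0.294), with a median of -0.04 (-0.10 without wild-type replicate 3 and -0.01 without wild-type replicate 1) and a mean of 0.24, the direction of its test. Of its 13 members 5 rose and 1 fell, also adjusted over the list alone, and 3 fell without wild-type replicate 3. Of these Gatm, the first enzyme of creatine synthesis, rose by 1.40 ± 0.10, Ckmt1 by 1.34 ± 0.08 and Ckb, the brain type of creatine kinase, by 0.97 ± 0.07, while the muscle type Ckm fell by 0.33 ± 0.07 (adjusted p = 0.00532; mean of its probe sets -0.10, not called). Slc25a5 (0.34; 0.12 and not called with plain probe sets) and Slc6a8 (0.24), chosen after their values were seen, rose too, and Slc6a8 was called only without wild-type replicate 2 among the fits that leave out an array (adjusted p up to 0.128). Alongside these lists, the sarcomere list, which serves as a marker of cardiomyocytes, had a median of -0.05, the macrophage markers 1.31, the fibroblast markers 0.64 and the endothelial markers -0.23.

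Regulators of mitochondrial genes fell in 9 of 20 cases and rose in 0, also adjusted over the list alone, with a median of -0.23 (adjusted p = 0.00389; adjusted p = 0.351 with an estimated correlation). Ppargc1a, the coactivator PGC-1α, fell from 11.58 ± 0.29 to 9.79 ± 0.30 (SD, n = 3), a log2 fold change of -1.79 ± 0.17 (adjusted p = 7.78e-05) or 3.46-fold, and its 5 probe sets gave -1.57 to -1.90. Klf15 fell by 1.38 ± 0.15, the fatty acid receptor Ppara by 0.87 ± 0.13, its partner Rxrg by 0.84 ± 0.09 and Tfb1m by 0.83 ± 0.12. The calls of Gabpa (-0.39), Rxra (-0.25), Esrra (-0.23) and Perm1 (-0.22) depended on single arrays. Gabpa was not called without wild-type replicate 2 (adjusted p = 0.0514) or caAkt replicate 2 (0.0519). Esrra was not called without any single array (adjusted p 0.0591 to 0.121), Rxra without any except caAkt replicate 2 (up to 0.120) and Perm1 without any except caAkt replicate 1 (up to 0.123). Without wild-type replicate 2, 5 regulators fell. The related coactivators Ppargc1b (-0.03 ± 0.10) and Pprc1 (0.12 ± 0.07), and Ppard (0.03), Nrf1 (-0.03), Tfb2m (0.03), Polrmt (-0.14), Yy1 (-0.06) and Esrrb (-0.15) were not called. Tfam (-0.23 ± 0.09, adjusted p = 0.0805) was called without caAkt replicate 1 (-0.30, adjusted p = 0.0484), as was Nrip1 (0.26; without it 0.35, adjusted p = 0.0445). Esrrg (-0.26, adjusted p = 0.0970) was called without wild-type replicate 3 (-0.37, adjusted p = 0.0123), and a dimmer probe set of it gave -1.13 (adjusted p = 0.000117 among all probe sets).

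**Figure D2:**
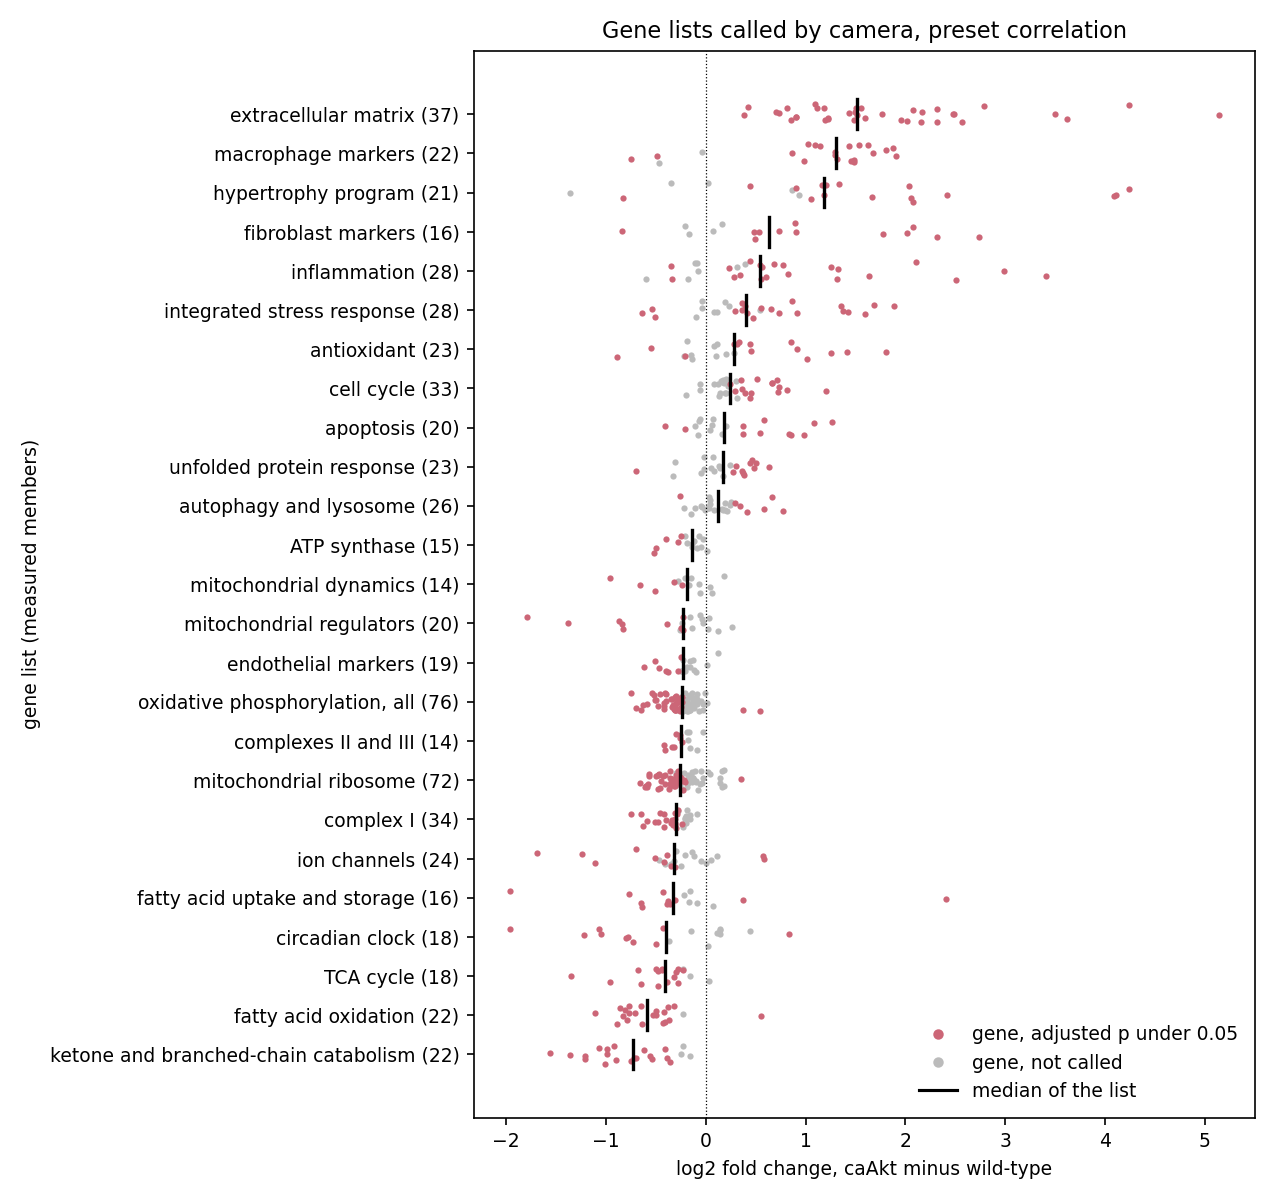
Log2 fold change of caAkt minus wild-type (horizontal axis) for each measured member of the 25 lists called by camera with the preset correlation (vertical axis, number of members in brackets). Red points are genes called at an adjusted p under 0.05, grey points are not called, and black bars mark list medians, which run from -0.73 for ketone and branched-chain catabolism to 1.51 for extracellular matrix.

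In the insulin, IGF and Akt pathway list, 6 of 28 genes rose and 6 fell (7 and 6 adjusted over the list alone), with a median of 0.03 (0.02 to 0.05 without single arrays), and the list was not called (adjusted p = 0.508). Akt1 itself is among those that rose. The adaptor Irs1 fell by 1.17 ± 0.07 (adjusted p = 4.58e-06) and the insulin receptor gene Insr by 1.04 ± 0.09, while the regulatory subunit Pik3r3 rose by 0.94 ± 0.09. Targets of FoxO factors, which Akt restrains, went both ways, and the list was not called (median -0.16, adjusted p = 0.184; -0.24 to -0.13 without single arrays). Of 28 members, 12 fell and 5 rose (13 and 7 adjusted over the list alone). Without wild-type replicate 2 or caAkt replicate 3, 7 fell, and without wild-type replicate 2 or 3 or caAkt replicate 2 or 3, 3 rose. Klf15 and Insr fell as above and the ubiquitin ligase Trim63 fell by 0.82 ± 0.09, whereas the cell cycle inhibitor Cdkn1a rose by 1.79 ± 0.16. The other members that rose were Fbxo32 (1.99-fold), Sesn3 (0.43), Txnip (0.44) and Tsc22d3 (0.50), all chosen after their values were seen. Txnip was called only without caAkt replicate 1 among the fits that leave out an array (adjusted p up to 0.0947), as was Tsc22d3 (up to 0.157), whose value was -0.16 and not called with plain probe sets. Pdk4, the kinase that inhibits pyruvate dehydrogenase, had a log2 fold change of 0.01 ± 0.20 (adjusted p = 0.967). Without wild-type replicate 3 it was -0.27 and called (adjusted p = 0.0470).

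The glucose transporter genes named beforehand went opposite ways. The transporter Slc2a1 (GLUT1) rose from 8.97 ± 0.15 to 9.89 ± 0.09, a log2 fold change of 0.92 ± 0.09 (adjusted p = 8.79e-05), and the insulin-responsive Slc2a4 (GLUT4) fell from 12.55 ± 0.07 to 11.84 ± 0.01, a log2 fold change of -0.71 ± 0.07 (adjusted p = 6.68e-05). Over the glucose transport and glycolysis list, 9 of 21 rose and 5 fell, also adjusted over the list alone, and the list was not called (median 0.19, adjusted p = 0.120). The platelet type phosphofructokinase Pfkp rose by 1.55 ± 0.07 and the lactate exporter Slc16a3 by 1.29 ± 0.10, while the muscle enolase Eno3 fell by 0.78 ± 0.07. Also lower, and chosen after their values were seen, were Pfkfb2 (-0.63), Ldhb (-0.53) and the muscle phosphofructokinase Pfkm (-0.34).

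Genes raised in cardiac hypertrophy were higher in caAkt hearts, beside macrophage markers with a median of 1.31 and fibroblast markers with 0.64. Of 21 measured, 15 rose and 1 fell (15 and 2 adjusted over the list alone), with a median log2 fold change of 1.19 (adjusted p = 2.36e-10; adjusted p = 0.279 with an estimated correlation). Besides Timp1, Nmrk2 and Lgals3, Tgfb2 rose by 2.07 ± 0.09. Timp1 and Tgfb2 also belong to the extracellular matrix list, so the results of these lists are not independent. The natriuretic peptide genes Nppa and Nppb rose by at least 2.42 ± 0.12, since Nppa reached 15.16, near the top of the scale, and by 1.16 ± 0.16, and the slow myosin heavy chain Myh7 by 1.34 ± 0.27 (adjusted p = 0.00578). The member that fell was Mybpc2 (-0.82), chosen after its value was seen, and 2 fell without wild-type replicate 2 or caAkt replicate 1. Skeletal actin Acta1 had a value of 0.86 ± 0.37 (adjusted p = 0.115), and 1.34 without wild-type replicate 2 (adjusted p = 0.00359). The adult myosin heavy chain Myh6 had a value of -0.20 ± 0.07 (adjusted p = 0.0645) at a probe set near the top of the scale (15.22 and 15.02), and the mean of its probe sets gave -0.50 and was called. Atp2a2, the calcium pump of the sarcoplasmic reticulum, had a value of -0.08 ± 0.07 (adjusted p = 0.401) at a probe set at 15.17 and 15.09. Its 3 dimmest probe sets, at 11.33, 10.94 and 7.96 in wild-type, gave -0.87, -1.52 and -1.38, and the mean of its 6 probe sets gave -0.71 and was called.

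**Figure D3:**
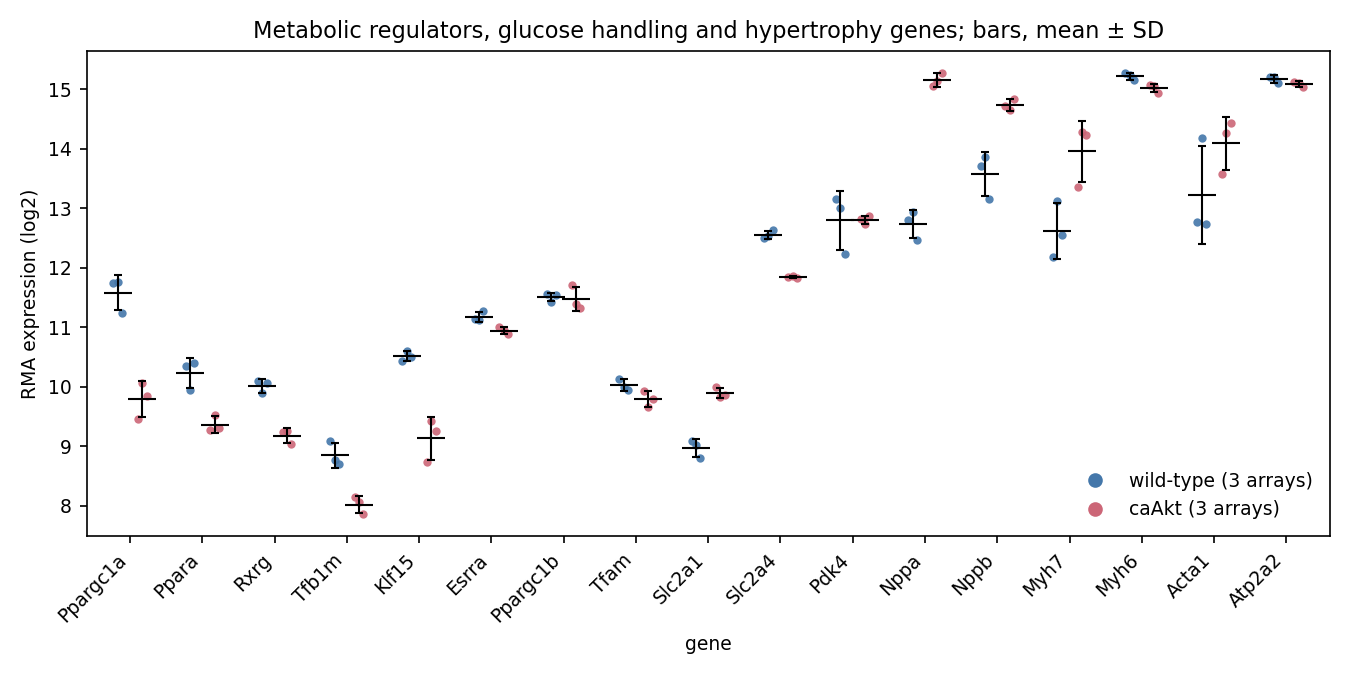
RMA expression (log2, vertical axis) of regulators of metabolism, glucose handling genes and hypertrophy genes (horizontal axis) on each array, with points for arrays (blue wild-type, red caAkt) and bars for the mean ± SD of 3 arrays. Ppargc1a stood at 11.58 in wild-type and 9.79 in caAkt and Nppa at 12.73 and 15.16, whereas Atp2a2 stood at 15.17 and 15.09.

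The sarcomere list was not called (median -0.05, adjusted p = 0.184; median -0.09 without wild-type replicate 3 and -0.02 without wild-type replicate 2), with 7 of 23 genes lower and 2 higher (8 and 3 adjusted over the list alone). It was called with all probe sets as rows (median -0.12, adjusted p = 0.0273). Myom2 and Tcap fell by 0.78 ± 0.14 and 0.67 ± 0.08, while desmin, Des, rose by 0.65 ± 0.09 and Smpx, chosen after its value was seen, by 0.37 ± 0.08. Of these 23 probe sets, 22 had a mean of at least 13 on the log2 scale, and the means reached 15.38, close to its top. Calcium handling genes fell in 9 of 22 cases and rose in 4 (11 and 4 adjusted over the list alone; median -0.27, adjusted p = 0.0618), and the list was called without caAkt replicate 1 (median -0.32, adjusted p = 0.0211). Hrc fell by 0.83 ± 0.07 and Fkbp1b rose by 0.61 ± 0.07. For Asph, the brightest probe set gave -0.87 and another -0.60, while dimmer ones gave 0.62 and 0.53, all called, and the mean of its probe sets was -0.08. Other members that rose, chosen after their values were seen, were the sodium-calcium exchanger Slc8a1 (1.13), Adcy5 (0.56, but 0.06 as the mean of its probe sets) and Atp2b1 (0.42). Cardiac ion channel genes fell in 9 of 24 cases and rose in 2 (14 and 2 adjusted over the list alone; median -0.31, adjusted p = 0.00298; adjusted p = 0.279 with an estimated correlation). Beside them, macrophage markers had a median of 1.31, fibroblast markers 0.64 and endothelial markers -0.23. Abcc9 and Kcnj8, subunits of the ATP-sensitive potassium channel that are also markers of mural cells, fell by 1.69 ± 0.08 and 0.70 ± 0.09. Kcnip2, a subunit of the transient outward channel, fell by 1.24 ± 0.13, and Kcnv2 by 1.11 ± 0.17. The members that rose, chosen after their values were seen, were Atp1b1 (0.58; -0.05 and not called with plain probe sets) and Kcne1 (0.58), which was not called without wild-type replicate 1 (adjusted p = 0.0648), caAkt replicate 1 (0.0990) or caAkt replicate 2 (0.0942).

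Several stress programs were higher, beside macrophage markers with a median of 1.31 and fibroblast markers with 0.64. In the list of ATF4-linked genes of amino acid and mitochondrial stress, 17 of 28 rose and 3 fell (18 and 3 adjusted over the list alone), with a median of 0.40 (adjusted p = 8.59e-07; adjusted p = 0.329 with an estimated correlation). Nupr1 rose by 1.89 ± 0.08, the folate enzyme Mthfd2 by 1.69 ± 0.13, Aldh18a1 of proline synthesis by 1.43 ± 0.08 and the amino acid transporter Slc7a5 by 1.38 ± 0.08. The members that fell, chosen after their values were seen, were Vldlr (-0.64), Slc7a1 (-0.54) and Stc2 (-0.50), and Vldlr was not called without caAkt replicate 3 (adjusted p = 0.0516). Antioxidant genes rose in 11 of 23 cases and fell in 3 (12 and 5 adjusted over the list alone; median 0.28, adjusted p = 0.00539; adjusted p = 0.355 with an estimated correlation). Mt2 rose by 1.81 ± 0.12, Gpx3 by 1.42 ± 0.07, Srxn1 by 1.26 ± 0.08 and Gpx1 by 0.92 ± 0.08. Those that fell were Gstm1 (-0.89), the mitochondrial peroxiredoxin Prdx3 (-0.54) and the mitochondrial superoxide dismutase Sod2 (-0.21), chosen after their values were seen. Sod2 was called only without wild-type replicate 3 among the fits that leave out an array (adjusted p up to 0.159). With all probe sets as rows the antioxidant list was not called (adjusted p = 0.116).

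Beside the same rise of macrophage markers (18 of 22 higher), unfolded protein response genes rose in 10 of 23 cases and fell in 1 (11 and 1 adjusted over the list alone; median 0.18, adjusted p = 0.0118; adjusted p = 0.524 with an estimated correlation). Sec61b rose by 0.64 ± 0.08 and Sdf2l1 by 0.51 ± 0.10, and Herpud1 fell by 0.70 ± 0.07. This list rested on single arrays: without wild-type replicate 3 it was not called (median 0.11, adjusted p = 0.0753, 3 lower), without wild-type replicate 1 its median was 0.28, and 6, 5 and 6 genes rose without wild-type replicate 2, caAkt replicate 1 and caAkt replicate 3. It was not called with the filter on dim probe sets (adjusted p = 0.0833) or by fry (adjusted p = 0.0986) either. Of 26 autophagy and lysosome genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.12, adjusted p = 0.0164; adjusted p = 0.362 with an estimated correlation; median 0.07 without wild-type replicate 3). The call was lost with plain probe sets (adjusted p = 0.212), the filter on dim probe sets (adjusted p = 0.0994) and renewed quantile normalization (adjusted p = 0.0884). The cathepsins Ctsb and Ctsd rose by 0.77 ± 0.08 and 0.59 ± 0.08. The cargo receptor Sqstm1 rose by 0.66 ± 0.07 at its brighter probe set and had a value of -0.07 at the other. Ulk1 (-0.26), chosen after its value was seen, was called only without wild-type replicate 1 or caAkt replicate 1, so 0 members fell without each of the other arrays (adjusted p up to 0.140). Apoptosis regulators rose in 9 of 20 cases and fell in 2 (10 and 2 adjusted over the list alone; median 0.18, adjusted p = 0.00539; adjusted p = 0.362 with an estimated correlation). With the filter on dim probe sets this list was not called (adjusted p = 0.101). Both the anti-apoptotic Bcl2 (1.27 ± 0.11) and the pro-apoptotic Bid (0.86 ± 0.11) rose, as did Casp12 (1.08 ± 0.09). Pmaip1 rose by at least 0.98 ± 0.11, a lower bound because its wild-type level of 4.44 lies within the Y-linked signal. Bcl2l11 (-0.40) and Diablo (-0.21), chosen after their values were seen, were the members that fell. Diablo was not called without any single array (adjusted p up to 0.117), nor was Bcl2l11 without any except the second replicates (up to 0.0698), so that 1 or 0 fell. Cell cycle genes rose in 15 of 33 cases and fell in 0 (17 and 1 adjusted over the list alone; median 0.24, adjusted p = 1.10e-06; adjusted p = 0.279 with an estimated correlation). Birc5 rose by 1.21 ± 0.15, Ccnd2 by 0.81 ± 0.11 and Cdk1 by 0.71 ± 0.09, and Top2a rose by 0.73 ± 0.08 at its brightest probe set, with -0.06 and 0.02 at the others.

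Extracellular matrix genes were higher without exception, beside the fibroblast and macrophage markers: all 37 measured members of the list rose, also adjusted over the list alone, with a median log2 fold change of 1.51 (adjusted p = 4.07e-33; adjusted p = 0.279 with an estimated correlation). The collagen gene Col1a1 rose from 10.82 ± 0.07 to 13.13 ± 0.07 (log2 fold change 2.31 ± 0.07, adjusted p = 2.85e-07), or 4.97-fold, and Mmp14 rose by 2.16 ± 0.08. Cytokine, chemokine and acute-phase genes rose in 19 of 28 cases and fell in 2 (21 and 3 adjusted over the list alone; median 0.55, adjusted p = 1.12e-07; adjusted p = 0.279 with an estimated correlation). The chemokine Ccl8 rose by 2.99 ± 0.12 and Il33 by 2.10 ± 0.09. Il6 rose by at least 2.50 ± 0.12, a lower bound because its wild-type level of 3.98 lies within the Y-linked signal. Nos3 (-0.33) and Cxcl12 (-0.35), chosen after their values were seen, were the members that fell. Nos3 was not called without wild-type replicate 2 or 3 or caAkt replicate 1 or 3 (adjusted p up to 0.105). Without wild-type replicate 3, caAkt replicate 1 or caAkt replicate 3, 1 member fell, and the mean of the probe sets of Cxcl12 was -0.13 and not called. Interferon-stimulated genes had a median of 0.09 and were not called (adjusted p = 0.234), except without caAkt replicate 3 (median 0.13, adjusted p = 0.0423; 0.05 without caAkt replicate 2). Among them Oasl2 rose by 0.68 ± 0.12 and Rsad2 fell by 0.60 ± 0.09. The angiogenesis and hypoxia list was not called (median -0.17, adjusted p = 0.178), with 8 of 22 genes lower and 4 higher, also adjusted over the list alone. Epas1 fell by 0.57 ± 0.08 and Pgf by 0.53 ± 0.07, while Adm rose by 0.71 ± 0.09. Slc2a1 rose as above, and so did Hif1a (0.71) and Egln3 (0.40), chosen after their values were seen. Egln3 was not called without wild-type replicate 2, caAkt replicate 1 or caAkt replicate 3 (adjusted p up to 0.0784).

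Markers of other cell types moved in different directions. Of 22 macrophage markers, 18 rose and 2 fell, also adjusted over the list alone, with a median of 1.31 (adjusted p = 3.09e-11; adjusted p = 0.351 with an estimated correlation). Lyz2 rose by 1.91 ± 0.10 to 13.51 ± 0.12, Cd68 by 1.88 ± 0.10, C1qb by 1.54 ± 0.09 and C1qa by 1.30 ± 0.08. Timd4 (-0.75) and Cd163 (-0.49) fell. They were chosen after their values were seen, and Cd163 was not called without wild-type replicate 1 (adjusted p = 0.0527) or caAkt replicate 1 (0.0715), which left 1 that fell. Of 16 fibroblast markers, 11 rose and 1 fell (11 and 2 adjusted over the list alone), with a median of 0.64 (adjusted p = 6.29e-06; adjusted p = 0.362 with an estimated correlation). Of these markers 4 also belong to another list, among them Col1a1 and Col1a2 (2.02 ± 0.08). Mfap4 rose by 2.74 ± 0.12 and Mfap5 by 2.08 ± 0.13, and Scara5 fell by 0.84, chosen after its value was seen. Endothelial markers fell in 7 of 19 cases and rose in 0 (10 and 0 adjusted over the list alone), with a median of -0.23 (adjusted p = 0.00135; adjusted p = 0.351 with an estimated correlation). Without wild-type replicate 2 or caAkt replicate 1, 4 fell. Aqp1 fell by 0.62 ± 0.09, Erg by 0.51 ± 0.08 and Kdr by 0.46 ± 0.08. Markers of mural cells (median -0.10, adjusted p = 0.491), lymphocytes and neutrophils (median -0.11, adjusted p = 0.571), and blood cells (median -0.14, adjusted p = 0.320) were not called as lists. Without single arrays their medians ranged over -0.16 to -0.03, -0.15 to -0.03 and -0.18 to -0.09. Of 9 blood cell markers 3 fell, also adjusted over the list alone, all of red cells: Alas2 (-1.04 ± 0.24), Hbb-b2 (-1.07 ± 0.35) and Slc4a1 (-0.99 ± 0.29), and the other 6 members were not called. Hbb-b2 was called only without caAkt replicate 1 (adjusted p up to 0.171) and Slc4a1 only without wild-type replicate 2 or caAkt replicate 1 (up to 0.119) among the fits that leave out an array, so that 1 fell without wild-type replicate 1 or 3 or caAkt replicate 2 or 3. Fat cell markers were not called either (median -0.27, adjusted p = 0.0906), though this list was called without wild-type replicate 1 (-0.26, adjusted p = 0.0336) or wild-type replicate 2 (-0.27, adjusted p = 0.0412). In it Car3 (log2 fold change -2.27 ± 0.30) and Adipoq (-1.73 ± 0.27) fell, with SDs of 0.74 and 0.65 among the wild-type arrays against 0.18 in caAkt.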

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

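Outside the genes compared above, 10092 probe sets had several gene symbols or none in the annotation used here. In the limma fit of all probe sets, 1140 of them differed between caAkt and wild-type, 427 higher and 713 lower. The change was at least 2-fold for 73 that were higher and 52 that were lower. They stand out because no comparison above uses them, and no explanation was tested for them.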

How the results depend on the processing

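The counts were within 1.5 times their values above under eBayes with trend and robust settings, the mean of a gene's probe sets, plain probe sets, the dim filter, both further normalizations and array weights. Renewed quantile normalization gave 2669 higher and 2708 lower, which turns the majority around, and the cause was not tested. Taking each probe set as a row gave 9023 changed, 5080 higher, 3943 lower and 1168 at least 2-fold, because 45037 rows were tested. A threshold of 0.01 gave 3255 changed and 1270 lower, by its construction. Leaving out single arrays gave 3984 to 4827 changed genes, 2369 to 2605 higher, 1615 to 2222 lower, 605 to 670 at least 2-fold and 25 to 26 lists, with 3912 to 4394 of the 5183 calls kept. The lists' fits under settings other than the estimated correlation and the block were chosen after seeing the data. The median log2 fold change of all genes was -0.04, and 0.01 with the dim filter. The medians of TCA cycle, fatty acid oxidation and oxidative phosphorylation genes ranged over -0.44 to -0.38, -0.63 to -0.52 and -0.27 to -0.20 without single arrays. With an estimated correlation camera called 0 of 45 lists (6 at an unadjusted p under 0.05), where medians of -0.41, -0.58 and -0.23 had adjusted p of 0.351, 0.355 and 0.447. That setting rests on 4 degrees of freedom. Fry called 31 lists, 24 of them among the 25 called by camera, and 43 in either direction. Lists called by fry but not by camera were those of energy transfer (fry adjusted p = 0.0192), glycolysis (0.00847) and insulin and IGF signalling (0.00587). The others were angiogenesis and hypoxia (0.0317), calcium handling (0.00957), fat cells (0.0142), and lung and thymus (0.0249). With plain probe sets the values of Akt1 (-0.29), Atp1b1 (-0.0465), Sqstm1 (-0.0660), Top2a (-0.0587) and Tsc22d3 (-0.16) changed sign, because other probe sets stand for these genes. Atp1b1 and Tsc22d3 were not called there. Pdk4 was -0.27 and called without wild-type replicate 3 and 0.193 without wild-type replicate 1, and the cause was not tested. Over all alternatives, named genes gave 3785 comparisons on the same side of the threshold, 222 no longer called, 38 newly called and 6 reversed, and the other lists gave 656, 33, 21 and 0. Reversed means that the sign differed and that either fit called the result, so it includes lost calls with a small opposite value. The autophagy list was lost with plain probe sets (adjusted p = 0.212), the dim filter (0.0994) and renewed quantile normalization (0.0884), the unfolded protein response list with the dim filter (0.0833) and fry (0.0986), the antioxidant list with all probe sets (0.116), the apoptosis list with the dim filter (0.101) and the clock list with the mean of probe sets (0.146). Lists gained with all probe sets were those of complex IV (adjusted p = 0.0496), glycolysis (0.0484), sarcomere (0.0273), calcium handling (0.00159) and fat cells (0.0134), and calcium handling was also called with the mean of probe sets (0.0261), the dim filter (0.0126) and renewed quantile normalization (0.0456). Means of 8.10% of genes lay at or under the highest Y-linked signal, which limits what can be seen at the low end.

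The replicate numbers gave residual correlations of 0.27, 0.03 and -0.12 between same-numbered arrays, and only wild-type replicate 1 correlated best with its own number. No pairing was evident, but so few pairs cannot exclude one. With a replicate block, 5141 genes changed, 2903 higher, 2238 lower and 627 at least 2-fold, and 26 lists were called (calcium handling gained, adjusted p = 0.0337), with medians of -0.41, -0.58 and -0.23 for the TCA cycle, fatty acid oxidation and oxidative phosphorylation genes.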

Other observations

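The tests of cardiomyocyte RNA against mitochondrial genes and against markers of other cell types were chosen only after the results were seen, and those of matrix genes, clock genes and array splits before.

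Genes of the circadian clock were lower as a list, with 9 of 18 lower and 1 higher (9 and 2 adjusted over the list alone), a median log2 fold change of -0.40 and an adjusted p of 0.0431 (adjusted p = 0.362 with an estimated correlation). The list was not called without wild-type replicate 1 (median -0.49, adjusted p = 0.0530) or caAkt replicate 1 (-0.30, adjusted p = 0.0556, 2 higher), nor with the mean of a gene's probe sets (adjusted p = 0.146). Ciart (log2 fold change -1.06 ± 0.09), Per3 (-1.05 ± 0.13), Tef (-0.80 ± 0.11) and Nr1d2 (-0.78 ± 0.11) fell. Among genes chosen after their values were seen, the output factor Dbp fell by 1.96 ± 0.30, while Arntl, the core activator, rose by 0.83 ± 0.15, with 0.06 from its plain probe sets. Dbp stood at 10.21, 9.22 and 8.72 on the caAkt arrays and at 11.27 to 11.40 in wild-type. A candidate explanation is a different hour of collection, which would raise genes of the opposite phase while output genes fall. The median of 5 opposite-phase genes was 0.14, against -0.79 for 10 output genes. The opposite-phase values ran from -0.14 (Cry1) to 0.83 (Arntl). The standard error over these members was 0.17, but it is that of their mean and does not measure the precision of the median. This comparison therefore neither shows a rise nor rules it out. On the caAkt arrays Arntl (8.19, 8.67, 8.86) and Nfil3 (8.08, 8.61, 8.76) rose in the order in which Dbp fell, whereas Npas2, Clock and Cry1 did not. Since the labels give no hour, an effect of genotype and an hour of collection cannot be told apart.

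Immediate early genes, which respond to handling of tissue, were not called as a list (median 0.04, adjusted p = 0.441; medians -0.02 without wild-type replicate 1 and 0.10 without caAkt replicate 1), yet Egr2 rose by 2.48 ± 0.10, Myc by 0.91 ± 0.12 and Maff by 0.77 ± 0.08, and Btg2 fell by 0.79 ± 0.09. Sterol and lipid synthesis genes were not called (median 0.08, adjusted p = 0.184; 0.04 to 0.12 without single arrays), with Sqle 0.56 ± 0.08 higher and Fdft1 lower (-1.17 ± 0.08). Markers of skeletal muscle had a median of -0.16 and a mean of 0.06 (adjusted p = 0.258, test direction down), with 1 of 12 higher and 2 lower, also adjusted over the list alone. Myl1, a fast skeletal and fetal myosin light chain, rose by 2.51 ± 0.12 to 14.52 ± 0.09, while Mylpf (-0.46 ± 0.08) and Atp2a1 (-0.29 ± 0.08) fell. Without wild-type replicate 1 or 2 or caAkt replicate 2 or 3, Atp2a1 was not called (adjusted p = 0.0545, 0.0907, 0.0765 and 0.0752), which left 1 lower. Epicardial markers had a median of -0.19 and a mean of 0.25 (adjusted p = 0.793, test direction down), with 2 of 10 higher and 2 lower (2 and 4 adjusted over the list alone). Krt18 rose by 2.94 ± 0.22 and Aldh1a2 by 1.03 ± 0.13, while Wt1 (-0.27 ± 0.08, adjusted p = 0.0366) and Upk3b (-0.45 ± 0.15, adjusted p = 0.0494) fell. Wt1 was called only without caAkt replicate 2 and Upk3b only without wild-type replicate 3 among the fits that leave out an array (adjusted p up to 0.124 and 0.175). This left 0 lower without wild-type replicate 1 (3 higher) or 2 or caAkt replicate 1 or 3, 1 without caAkt replicate 2, and 3 without wild-type replicate 3. Atrial and conduction markers (median 0.03, adjusted p = 0.276) included Dkk3, which rose by 1.24 ± 0.17, and their median ranged from -0.13 without wild-type replicate 2 to 0.19 without wild-type replicate 3, with -0.02 without caAkt replicate 1. Lung and thymus markers had a median of -0.19 (adjusted p = 0.261; -0.13 without wild-type replicate 2).

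Mitochondrial genes fell while markers of macrophages and fibroblasts rose, which a lower share of cardiomyocyte RNA might produce, and that would lower sarcomere genes by as much. The fatty acid oxidation median (-0.58, 22 genes) differed from that of 9 sarcomere genes in its range of brightness (-0.19) by -0.397 (permutation p = 0.0054), and the oxidative phosphorylation median (-0.23, 76 genes) differed by -0.166 from 17 of them (-0.07, permutation p = 0.0021). A mean level under 13 was found for 14 fatty acid oxidation genes (median -0.74; -0.50 for the 8 brighter ones) but only 1 sarcomere gene, yet over the shared range of brightness the median of 12 fatty acid oxidation genes still differed by -0.397 (permutation p = 0.013). If the other cell types kept their proportions, a lower cardiomyocyte share would raise their markers alike. Endothelial markers lay below macrophage markers by a difference of -1.54 (permutation p = 0.00022) and below fibroblast markers by -0.87 (permutation p = 2e-05), which goes against such a uniform rise only. More macrophages and fibroblasts would lower the cardiomyocyte share and endothelial markers together, so the marker values cannot decide on that share. The fatty acid oxidation comparison covers levels of 12.44 to 14.09. Unless sarcomere genes rose per cell, it argues against that share as the whole cause for the fatty acid oxidation genes. Its p-value treats genes, not samples, as the units. The oxidative phosphorylation comparison reaches 15.11 and is not relied on. At such levels the probe sets of Atp2a2 (-0.08, mean of all -0.71) and Myh6 (-0.20, mean -0.50) showed less of a fall. A lower share as part of the cause, a change of sarcomere genes per cell and an effect of genotype stay open.

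All 37 matrix genes rose, which a larger share of fibroblast RNA might produce. The matrix median (1.51) exceeded that of 12 fibroblast markers outside the list (0.49) by 1.02 (permutation p = 0.0052, with genes rather than samples as the units). This goes against an equal rise of all fibroblast genes. The fibroblast markers as a whole ranged from -0.84 to 2.74, however, so the comparison cannot decide on a larger share of some fibroblasts. A change of fibroblasts themselves, or of other cells that make matrix, stays open, and genotype is one possible source.

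Of the 10 splits of the 6 arrays into 3 and 3, the real one (1 of the 10) called 5183 genes with limma and the highest of the others 0 (110 to 569 genes at an unadjusted p under 0.05, against 7156). Each of the other splits mixes both genotypes, so genotype differences enter its residual spread and lower its count. The splits are also too few for a share under 0.05.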
